A study of Homo sapiens with 187 samples.

How the data were processed

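SLAM-seq libraries of the human myeloma line KMS-11 were analysed from the SlamDunk count tables that the authors deposited, 1 per library, 187 in all. Per the labels' protocols, cells were labelled with 4-thiouridine at 100 µM for 1 h, the RNA was treated with iodoacetamide, and 3' end libraries were made with a QuantSeq kit. Reads were checked with FastQC 0.11.9, trimmed with Trim Galore 0.6.4 and aligned to GRCh38/hg38, per the submitters' processing notes. The notes give no SlamDunk version, aligner settings or filters. Replicates were not pooled, and the doses were dTAGv1 at 100 nM, doxycycline at 100 ng/ml, EPZ-6438 at 200 nM and MAK-658 at 50 nM, per the labels.

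The deposited values are counts per RefSeq transcript, per the file headers: all reads, reads with T to C conversions, covered T and converted T. Reads with conversions stand for newly synthesised RNA and all reads for total RNA. The tables hold 95582 transcripts, of which 46332 match 1 gene symbol of the RefSeq table given with the data, giving 18829 genes, 17254 of them with reads. The transcripts without a symbol held 34.7% of the reads summed over transcripts, and 16.4% were the same values as a named transcript. Transcripts of a gene often carry the same reads: of 11237 genes with over 10 reads per library, 6300 have several transcripts, and these are identical in 4029. Fixed before the data were examined was a sum over a gene's transcripts. Because such a sum counts a read several times, the transcript with the most reads stands for its gene here. The sum is an alternative. For 80 genes that transcript had the same reads as one of another gene. The tables list 0 multimapped reads.

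Depth was 8.15 to 33.2 M gene reads per library and 0.307 to 2.50 M gene reads with conversions, which were 3.17% to 10.4% of the reads. In the hours-scale course the median depth was 10.4 M in replicate 1 and 28.1 M in replicate 2. Covered T per read had a median of 24.0, and 7 libraries, all of replicate 2, lay more than 2 scaled median absolute deviations (1.16) below it, under 21.7. The first principal component of the libraries held 34.2% of the variance and had an absolute Spearman correlation of 0.786 with covered T per read. Reads carry no molecular identifiers in these tables, so floors and counting intervals cover counting error only.

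Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalisation of the reads tested, filterByExpr at a minimum count of 10, and the quasi-likelihood F test at a Benjamini-Hochberg adjusted p of 0.05. All conditions of a part of the series entered 1 fit with the clone or line as an additive term, since the series design treats both clones as biological replicates. For the inhibitors the fit held 64 libraries, their 48 and the 16 days-scale libraries of the clones, which are the only ones with dTAGv1 alone. Reconstitution and inhibitor effects are means over 7, 14 and 21 d. In all 23 comparisons were made. Differences between responses were tested as interactions. Parental libraries of the knockout part read "KMS11#6" in their file headers and were used as labelled.

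The NSD2-dependent sets were genes at an adjusted p under 0.05 and a log2 fold change of −1 or less, taken from the days-scale course for the reconstitution lines and from the reconstitution lines for the inhibitors, so that set and effect come from separate libraries. Medians of a set in the 6 combinations of clone and day were tested with an exact two-sided sign-flip test, and compared with 1000 random sets matched on mean expression. Gene lists, 30 in number and fixed before the data were examined, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. Adjustment was over all 593 lists and comparisons together. Of 593 tests 91 passed at the preset correlation and 28 of these also with the estimated one.

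Genes named in the text follow a rule also fixed before the data were examined. They are the 10 largest rises and falls per comparison among genes past the test with at least 10 mean reads and the same sign in both clones, up to 4 members per list, the earlier reported NSD2 targets, chromatin modifiers of H3K36 and H3K27, and NSD2. The genes printed are a part of these. Folds against a group without reads are bounds against a floor of 3 reads over the group, and those with 1 to 3 reads are ratios with a 95% exact counting interval.

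Scripts were tested on simulated data, with 200 genes changed 2-fold in counts drawn from the real means and library sizes. At 2-fold, the share recovered was 39.9% at 72 h, 63.6% at 21 d, 87.8% for NSD2WT, 87.4% for EPZ-6438 and 66.3% for the knockout. Alternatives tried were DESeq2 1.42.0, scaling by total reads, no filter, sums over transcripts, replicate number as a block, cell means, summed libraries, single clones, single days, only the libraries compared, and each library left out in turn. Covered T per read as a covariate, alone or with the block, and the fit without the 7 libraries low in it were added after the data were seen. Tables were built with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Converted and covered T were used only for conversion rates and library checks.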

Results

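KMS-11 is an established human myeloma cell line with the t(4;14) translocation, which places NSD2, the gene of a histone H3 lysine 36 methyltransferase, under immunoglobulin enhancers. The series measured newly synthesised RNA by SLAM-seq in 187 libraries of these cells. Cells took up 4-thiouridine at 100 µM for 1 h, and alkylation of the extracted RNA then turned the labelled uridines into T to C conversions in 3' end reads. In 2 clones, numbered 8 and 11, NSD2 carried a tag through which dTAGv1 at 100 nM degrades the protein. The libraries fall into 5 parts. A course over hours had 30 libraries at 0, 2, 8, 24 and 72 h of dTAGv1, and a course over days had 24 at 0, 7, 14 and 21 d, each in parental cells and both clones. A reconstitution part had 80 libraries of clones with a doxycycline-inducible NSD2WT or NSD2Y1179A, the latter changed in the catalytic domain. An inhibitor part had 48 libraries given EPZ-6438 or MAK-658, both inhibitors of Polycomb repressive complex 2 (PRC2), with or without dTAGv1. A knockout part had 3 NSD2 knockout clones and 2 parental libraries. Other groups held 2 libraries each. Gene reads per library ranged from 8.15 to 33.2 M, of which 0.307 to 2.50 M carried T to C conversions.

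The NSD2 transcript is not the target of dTAGv1, which acts on the tagged protein, so its reads do not measure the depletion. In clone 8 NSD2 had 617 ± 125 T to C reads per M at 0 h and 522 ± 99.6 at 72 h (mean ± SD, n = 2). In the knockout clones NSD2 had 155 ± 31.2 total reads per M (mean ± SD, n = 3) against 300.2 ± 6.86 in their parental libraries (n = 2). This fall of the total reads passed the edgeR test (log2 fold change −0.96, SE 0.11, adjusted p = 1.0e-05). Newly synthesised NSD2 RNA did not show it relative to other labelled reads, with 503 ± 74.8 against 454 ± 71.7 T to C reads per M. Scaled by total reads instead, all genes of this comparison shifted by a median log2 fold change of −0.87. Whether synthesis of NSD2 RNA fell can therefore not be told from these values. The 3' tag can lie outside the edited part of the gene, so neither value measures the loss of NSD2 protein.

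**Figure D1:**
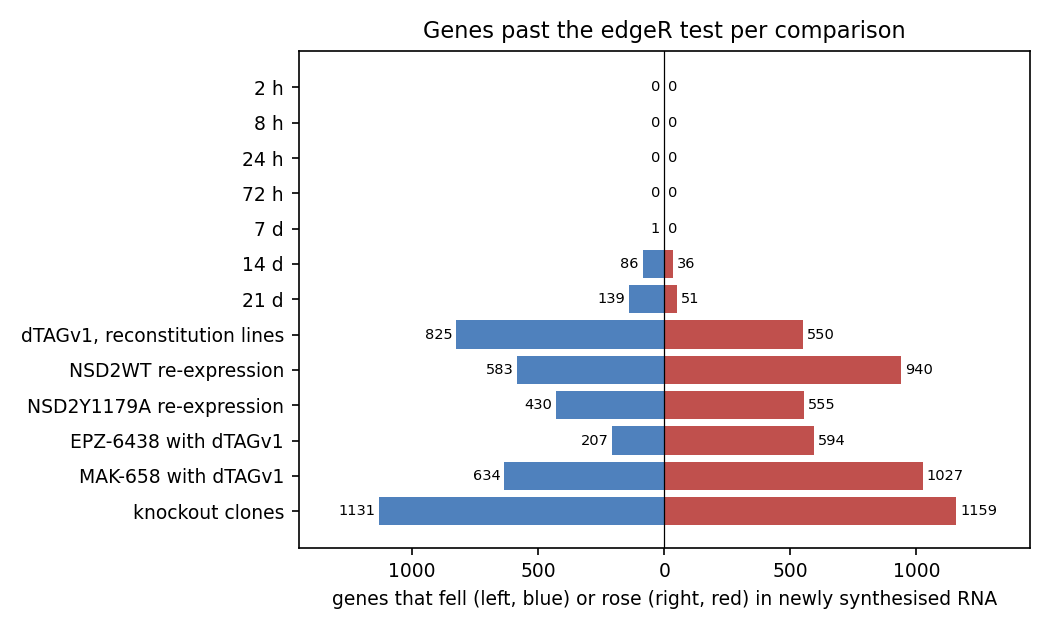
Genes past the edgeR test in newly synthesised RNA, one bar pair per comparison, with falls to the left and rises to the right in numbers of genes. No gene passed from 2 to 72 h, 1 fell at 7 d, and 86 and 139 fell at 14 and 21 d.

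The course over hours asks which transcription changes first when NSD2 protein is lost. No single gene rose or fell past the test at any of the 4 times, in tests that would miss many 2-fold changes. Genes of TGF-beta and BMP signalling lay lower as a group at 72 h, though none of them passed over all genes. Earlier reported NSD2 targets showed no shift that passed in newly synthesised RNA. The edgeR quasi-likelihood test called 0 of 9684 genes at 2, 8, 24 and 72 h, while 161, 384, 205 and 481 genes had an unadjusted p under 0.05. DESeq2 called 0, 0, 0 and 1 gene, and edgeR without the expression filter 6 at 72 h. Leaving out the 0 h library of clone 11, replicate 1, left 1 gene at 72 h. In simulated libraries of this design the 72 h test recovered 39.9% of genes changed 2-fold, and 67.0% of those expressed above the median.

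Among the 19 tested genes of TGF-beta and BMP signalling at 72 h, 0 passed over all genes and 2 fell when adjusted over the list alone. Their median log2 fold change was −0.22, and camera placed the list below other genes (adjusted p = 0.00023), with adjusted p = 0.028 with an estimated correlation. ID1, a direct target of BMP receptors, had a log2 fold change of −0.79 (SE 0.19, adjusted p = 0.74), from 1145 ± 205 to 661 ± 88.4 T to C reads per M (mean ± SD, n = 4 each). BMP2, a ligand, and ACVR1, a type I receptor, had log2 fold changes of −0.77 and −0.52, and the ligand TGFB2 had −1.44; their adjusted p was 0.97. Immediate early genes had a median of −0.31 (adjusted p = 1.2e-05), which did not hold with an estimated correlation (adjusted p = 0.26). JUN of that list had −0.46, also short of the test (adjusted p = 0.97). The 4 tested members of the earlier reported NSD2 targets, CCND2, PAK1, RRAS2 and TGFA, had a median of −0.37 (adjusted p = 0.26).

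In total RNA at 72 h, which also holds transcripts made before the label, 2 of 11716 genes passed, against 12 with DESeq2 and 0 when the 2 libraries of a clone and time were summed. IL6R, the interleukin 6 receptor, rose (log2 fold change 0.87, SE 0.12, adjusted p = 0.0047) from 19.8 ± 2.41 to 34.5 ± 4.83 reads per M (mean ± SD, n = 4 each). PRKCB, protein kinase C beta, fell (−0.78, SE 0.10, adjusted p = 0.0032). Of 5 tested earlier reported NSD2 targets 0 passed over all genes in total RNA. Adjusted over the list alone 3 fell, and the list median was −0.47. The parental cells, without the degradable allele, measure dTAGv1 itself: 0 of 9881 genes passed at 72 h with edgeR or DESeq2, and 737 had an unadjusted p under 0.05. Without the parental 72 h library of replicate 1, 372 genes passed. The response of the clones minus that of parental cells gave 0 of 10235 genes with edgeR and with DESeq2, with 338 at an unadjusted p under 0.05. In that difference 0 of 28 gene lists passed with camera. The lower TGF-beta and BMP genes of the clones were thus not shown to go beyond parental cells. These tests have little power, since in simulated libraries they recovered 3.63% and 2.54% of genes changed 2-fold.

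**Figure D2:**
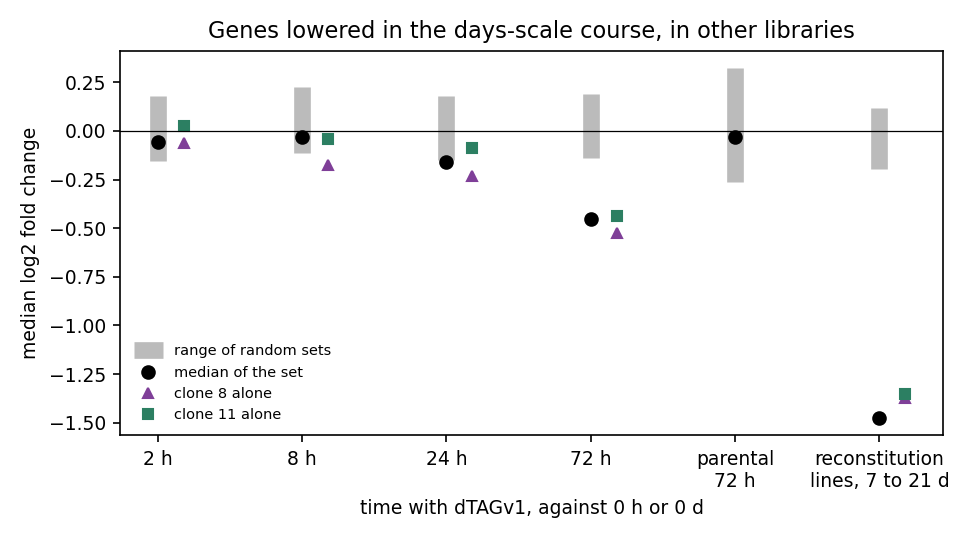
Median log2 fold change of the 76 genes lowered over days, at each time of the hours-scale course, in parental cells and in the reconstitution lines; grey bars give the range of 1000 random sets matched on expression. The set reached −0.45 at 72 h and −1.47 in the reconstitution lines.

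Genes lowered over days were already lower at 72 h as a set. The set holds the 76 genes that fell at least 2-fold in the mean of 7, 14 and 21 d in the days-scale course, a separate group of libraries. Its median log2 fold change was −0.06 at 2 h, −0.03 at 8 h, −0.16 at 24 h and −0.45 at 72 h. At 72 h 73 of the 76 genes lay below 0, and the median was −0.53 in clone 8 and −0.44 in clone 11. Random sets matched on expression ranged from −0.14 to 0.19 at that time. At 24 h the set also lay below all of them, by little (−0.162 against a lowest of −0.148). In parental cells the same genes had a median of −0.03 at 72 h, inside the random range.

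The course over days asks what follows when NSD2 stays depleted. Falls outnumbered rises and grew in number with time. Large falls included those of GLI3, TSPAN18 and COL27A1. No gene list had a call at 7, 14 or 21 d that held with an estimated correlation. At 7 d 1 of 9153 genes passed, GLI3, the Hedgehog pathway transcription factor (log2 fold change −1.74, SE 0.29, adjusted p = 0.027). That call was kept only without the clone 8 library at 0 d, replicate 2, and was lost without any 1 of the other 7 libraries compared. The count was 0 without clone 8 at 0 d, replicate 1, or at 7 d, replicate 2, and without clone 11 at 0 d, replicate 1 or 2, or at 7 d, replicate 1. At 14 d 36 genes rose and 86 fell, and at 21 d 51 rose and 139 fell, of which 20 and 103 changed at least 2-fold. Scaled by total reads, all genes shifted by a median of 0.14 at 14 d and 0.18 at 21 d, and the counts became 70 rises with 46 falls and 140 rises with 87 falls. The 14 d count of 122 depended on single libraries. It was 60 without the clone 8 library at 0 d of replicate 2, and 60 and 61 without those at 14 d of replicates 1 and 2. Without the clone 11 libraries of replicates 1 and 2 it was 62 and 77 at 0 d, and 61 and 210 at 14 d. Without clone 11 at 21 d, replicate 2, the 21 d count was 121.

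At 21 d GLI3, on chromosome 7, had fallen further (log2 fold change −3.39, SE 0.34, adjusted p = 7.1e-07), from 44.5 ± 10.9 to 4.30 ± 1.20 T to C reads per M (mean ± SD, n = 4 each). The tetraspanin TSPAN18 fell by 3.34 and the zinc finger gene ZNF618 by 2.93 on the log2 scale. COL27A1, a fibrillar collagen, fell by 2.91 (SE 0.29, adjusted p = 6.6e-07), and the RNA-binding protein gene CELF4 by 2.84. The potassium channel subunit KCNS3 fell by 2.79, the somatostatin receptor SSTR2 by 2.78, the receptor scaffold GRIP1 by 2.75 and the microtubule protein MAP1B by 2.71. Among rises, ADM, which encodes the vasodilator peptide adrenomedullin, rose by more than any other named gene (2.53, SE 0.36, adjusted p = 1.0e-04), from 13.2 ± 4.36 to 78.1 ± 36.2 T to C reads per M. SCNN1G, a subunit of the epithelial sodium channel, rose by 2.14, and the metalloproteinase gene MMP11 by 1.45. At 14 d COL27A1 had fallen by 2.29 and GLI3 by 2.60, with JPH1, a junctional membrane protein gene, fallen by 2.64. LPXN, leupaxin, had risen by 1.62 at 14 d, SETDB1, which encodes an H3K9 methyltransferase, by 0.91, and the ribonucleotide reductase subunit RRM1 by 0.65.

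Of the 4 tested earlier reported NSD2 targets, 1 fell at 21 d (3 adjusted over the list alone), and the list median was −1.10 (camera adjusted p = 0.0013), a call lost with an estimated correlation (adjusted p = 0.062). TGFA, a ligand of the EGF receptor, fell by 2.12 on the log2 scale (SE 0.33, adjusted p = 0.00039). CCND2, cyclin D2, stayed at 0.03, and PAK1 and RRAS2 had −1.12 and −1.07 without passing. Of 14 adhesion genes 3 fell (5 adjusted over the list alone), N-cadherin CDH2 by 2.34 (adjusted p = 0.0076), with a list median of −0.47 (adjusted p = 0.0042; adjusted p = 0.054 with an estimated correlation). Of 19 integrated stress response genes 1 fell (7 adjusted over the list alone). This was ATF3, by 1.24, and the list median was −0.29 (adjusted p = 0.00084; adjusted p = 0.13 with an estimated correlation). Of 17 immediate early genes 4 fell and 1 rose, JUN falling by 1.15 and ID2 rising by 0.64, with adjusted p = 0.043, lost with an estimated correlation (adjusted p = 0.25). Wnt pathway genes had 1 fall of 19, the receptor FZD8 by 2.35 (adjusted p = 7.8e-05), and 6 adjusted over the list alone. TGFBR3, the co-receptor betaglycan, fell by 1.67. The myeloid transcription factor CEBPA fell by 0.98, while the chemokine receptor CCR1 and the B cell coactivator POU2AF1 rose by 0.86 and 0.88. Interferon response and mitosis genes had 0 calls among 15 and 30 and medians of 0.34 and 0.15 (camera adjusted p = 0.041 and 0.014), lost with an estimated correlation (adjusted p = 0.15 and 0.35).

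Total RNA at 21 d had 307 rises and 643 falls among 11141 genes. Its counts do not compare directly with those of newly synthesised RNA, since simulated 2-fold changes were recovered for 82.9% of genes in total RNA and 63.6% in newly synthesised RNA. ADM rose by 2.98 (SE 0.38, adjusted p = 6.4e-05) and TGFA fell by 1.69 (SE 0.17, adjusted p = 8.7e-06). Of 5 tested earlier reported NSD2 targets 4 fell in total RNA, TGFA among them, and the list median was −1.44. In parental cells 0 of 9464 genes passed at 21 d with edgeR or DESeq2, with 177 at an unadjusted p under 0.05, and all genes shifted by a median of −0.11 when scaled by total reads. The parental test recovered 0% of simulated 2-fold changes, and 68 genes passed when the parental 7 d library of replicate 2, low in covered T, was left out of the fit, so an effect of dTAGv1 itself on other genes is not excluded. The 76-gene set showed none, with a median of 0.08 in these cells, inside the range of random sets (−0.21 to 0.18), with 32 genes below 0. The response of the clones minus that of parental cells passed for 1 rise and 24 falls among 9841 genes at 21 d. GLI3 (log2 difference −3.36, SE 0.47, adjusted p = 0.00055) and CELF4 (−3.18, SE 0.52, adjusted p = 0.0022) were among the falls whichever of the compared libraries was left out. That count depended on the parental libraries: it was 6 and 14 without replicate 1 and 2 at 0 d, 10 and 15 without replicate 1 and 2 at 21 d, and 51 without replicate 2 at 7 d. Under scaling by total reads all genes shifted by a median of 0.31 in this comparison. The 4 NSD2 targets had a median difference of −0.91 (adjusted p = 0.026; adjusted p = 0.13 with an estimated correlation).

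The reconstitution lines without doxycycline give a separate measurement of depletion, with 24 libraries at 7 to 21 d of dTAGv1 against 8 at 0 d. This part held no parental cells, and no libraries without compound after 0 d. Time in culture and dTAGv1 itself were therefore not separated from depletion. Falls again exceeded rises. Genes that fell in the days-scale course fell here too, and integrated stress response genes lay lower as a group. Of 10012 genes 550 rose and 825 fell, and 25 and 246 of these changed at least 2-fold. With scaling by total reads the counts were 434 rises and 328 falls. Of the 137 genes that fell in the mean over days in the days-scale course, 123 also fell here, where independent lists would share 10.0. Of its 49 rises, 32 also rose here, where independent lists would share 2.87. The 76-gene set had a median log2 fold change of −1.47, and 68 of its genes fell.

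The largest falls in these lines included the neuroligin gene NLGN4X (log2 fold change −3.64, SE 0.33, adjusted p = 1.3e-13) and PRKCB (−3.50, SE 0.30, adjusted p = 1.1e-14). PRKCB dropped from 15.4 ± 4.31 (n = 8) to 1.64 ± 1.40 (n = 24) T to C reads per M (mean ± SD). PRKAA2, a catalytic subunit of AMP-activated kinase, fell by 2.90, the activin family gene INHBE by 2.72, GLI3 by 2.55, the potassium channel gene KCNQ3 by 2.52, FAM107B by 2.41 and TSPAN18 by 2.31. Rises included BAIAP2, which encodes an adaptor of actin remodelling (2.52, SE 0.62, adjusted p = 0.0026), and the muscle protein gene TTN (1.77). ADM rose by 1.34, SCNN1G by 1.24 and E2F7, a cell cycle repressor, by 1.21. Of 19 integrated stress response genes 7 fell (10 adjusted over the list alone, with 1 rise), and the list had adjusted p = 1.4e-05, which held with an estimated correlation (adjusted p = 0.0013). CHAC1, which degrades glutathione, fell by 1.55, ALDH1L2, a mitochondrial folate enzyme, by 1.38, the cystine transporter SLC7A11 by 1.35 and ATF3 by 1.32. Of 23 cholesterol synthesis genes 10 fell (13 adjusted over the list alone), including HSD17B7 by 0.75 and STARD4 by 0.93 (adjusted p = 0.00082 for the list; adjusted p = 0.25 with an estimated correlation). Of 24 PRC2 targets 5 fell, among them FOXC1 by 0.61, and 1 rose (1 rise and 7 falls adjusted over the list alone). TGFA fell by 1.53, JUN by 0.68, EGR1 by 1.25, CDH2 by 1.28, JAM3 by 1.16 and CEBPA by 1.19. CCND2 and RRAS2 did not pass. Among chromatin genes the DNA methyltransferase DNMT3B fell by 0.37, PSIP1, a reader of H3K36 methylation, rose by 0.69, and 25 of the 31 tested did not pass. POU2AF1 rose by 0.71.

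Re-expression of NSD2WT in depleted cells asks which changes the active protein turns back. NSD2 reads did not show the induction of either construct, with log2 fold changes of 0.10 for NSD2WT (adjusted p = 0.45) and 0.24 for NSD2Y1179A (adjusted p = 0.055), so their amounts, and whether these were equal, are not known here. NSD2-dependent genes rose, immediate early genes and MAPK output lay higher as groups, and most mitosis genes fell. Depleted cells without re-expression were given no doxycycline, so an effect of doxycycline itself is not separated here. Of 10012 genes 940 rose and 583 fell, and 349 and 27 of these changed at least 2-fold. The counts were 626 rises and 178 falls when scaled by total reads. CACNA1A, a calcium channel gene, rose most among the examples (log2 fold change 4.37, SE 0.30, adjusted p = 2.9e-19), from 3.51 ± 3.50 to 53.9 ± 18.8 T to C reads per M (mean ± SD, n = 12 each). PRKCB rose by 4.04 and PRKAA2 by 2.86, both lowered with dTAGv1 alone. BAIAP2, already raised with dTAGv1 alone, rose by a further 3.54. The connexin gene GJC1 rose by 2.83 and the sodium channel gene SCN8A by 2.78. CBLN2, cerebellin 2, fell by 2.49 (SE 0.19, adjusted p = 1.5e-17), the chloride channel gene BEST3 by 1.39, and the integrin ITGA4, through which plasma cells bind stroma, by 1.21.

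Of 30 mitosis genes 28 fell with NSD2WT (29 adjusted over the list alone), with a median of −0.62 (camera adjusted p = 4.8e-25; adjusted p = 0.00043 with an estimated correlation). The kinesins CENPE and KIF20A fell by 0.95 and 0.86, the spindle protein ASPM by 0.92 and the checkpoint kinase TTK by 0.85. Of 30 S phase genes 8 fell (11 adjusted over the list alone), among them RRM2 by 0.37 and TYMS by 0.51, with adjusted p = 0.0011, lost with an estimated correlation (adjusted p = 0.38). Of 4 NSD2 targets 3 rose (3 adjusted over the list alone; adjusted p = 2.3e-06; adjusted p = 0.00029 with an estimated correlation): TGFA by 2.44, CCND2 by 0.73 and PAK1 by 0.72. Of 24 canonical PRC2 targets 9 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 0.00026; adjusted p = 0.0019 with an estimated correlation). GATA2 rose by 2.47, GATA3 by 2.04 and HOXC9 by 2.13, and WNT5A fell by 0.94. Of 19 immediate early genes 10 rose (10 adjusted over the list alone; adjusted p = 1.5e-05; adjusted p = 0.028 with an estimated correlation), EGR1 by 1.57, ID1 by 1.41 and JUN by 1.21. Of 15 MAPK output genes 8 rose (8 adjusted over the list alone; adjusted p = 6.9e-06; adjusted p = 0.029 with an estimated correlation), PHLDA1 by 1.92, ETV5 by 1.32 and DUSP5 by 1.04. Of 5 B cell genes 3 rose (5 adjusted over the list alone; adjusted p = 0.0013; adjusted p = 0.0083 with an estimated correlation): SPIB by 1.34, ID3 by 1.17 and IRF8 by 0.85. Of 15 plasma cell genes 4 fell and 1 rose. The immunoglobulin joining chain JCHAIN fell by 1.10, MZB1 by 0.75 and SDC1, which encodes CD138, by 0.66, and PSIP1 fell by 0.73.

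The same comparison with NSD2Y1179A asks what the protein does without its catalytic activity. Most NSD2-dependent genes did not pass, while mitosis and unfolded protein response genes lay lower as groups. Of 10012 genes 555 rose and 430 fell, and 99 and 12 of these changed at least 2-fold. Scaled by total reads, all genes shifted by a median of −0.24 and the counts were 123 rises and 1294 falls. SAMD11 rose by 2.68, SSTR2 by 2.39 (SE 0.17, adjusted p = 3.3e-18) and PRKCB by 2.26, followed by SATB1, a chromatin organiser gene, by 1.95 and the ubiquitin-like UBD by 1.74. JCHAIN fell by more than any other named gene (−1.70, SE 0.12, adjusted p = 3.3e-18), from 533 ± 82.4 to 167 ± 64.0 T to C reads per M (mean ± SD, n = 12 each). FGF9 fell by 1.42, CBLN2 by 1.31 and PPARGC1A, a coactivator of mitochondrial biogenesis, by 1.24. Of 30 mitosis genes 12 fell (15 adjusted over the list alone; adjusted p = 7.2e-12; adjusted p = 0.028 with an estimated correlation), including KIF11 by 0.62, TTK by 0.57 and cyclin A2 CCNA2 by 0.51. Of 19 unfolded protein response genes 3 fell (10 adjusted over the list alone; adjusted p = 5.0e-05; adjusted p = 0.026 with an estimated correlation), with PDIA4 falling by 0.65 and MANF by 0.62. Of 19 TGF-beta and BMP genes 7 rose (9 adjusted over the list alone, with 1 fall; adjusted p = 2.5e-05; adjusted p = 0.051 with an estimated correlation), TGFB2 by 1.57, ID1 by 1.15 and BMPR2 by 0.91. Of 15 plasma cell genes 5 fell (adjusted p = 9.6e-05; adjusted p = 0.054 with an estimated correlation), and 6 fell and 1 rose adjusted over the list alone. SDC1 fell by 0.82 and MZB1 by 0.59. Of 23 cholesterol synthesis genes 9 fell (11 adjusted over the list alone), among them INSIG1 by 0.65 (adjusted p = 1.6e-05 for the list; adjusted p = 0.13 with an estimated correlation). The proapoptotic genes BMF and BBC3 rose by 1.21 and 0.99, and JARID2, a PRC2 subunit gene, by 0.66. TGFA, PAK1 and RRAS2 did not pass, and CCND2 rose by 0.37.

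The direct test of NSD2WT minus NSD2Y1179A passed for 204 of 10012 genes, 147 higher and 57 lower with NSD2WT. These were 201 and 6 when scaled by total reads, which shifted all genes by a median of 0.27. BAIAP2 (log2 difference 3.62, SE 0.59, adjusted p = 5.3e-05), FAM107B (3.31) and INSM1, a neuroendocrine transcription factor gene (3.13), were higher with NSD2WT, as were GJC1 (2.63), SCN8A (2.56), GATA2 (2.45), COL27A1 (2.34) and TGFA (1.88). Of 16 adhesion genes 3 were higher: ITGA6 (1.33), CDH2 (1.27) and JAM3 (1.21). CEBPA (0.81) and the PRC2 target FOXC1 (0.68) were also higher. TTN (−1.87), CBLN2 (−1.18) and PSIP1 (−1.06) were lower. Of 5 MHC class II genes 2 were lower (3 adjusted over the list alone; adjusted p = 9.2e-05; adjusted p = 0.052 with an estimated correlation), among them HLA-DRA (−0.85). Mitosis genes were lower, with a median of −0.27 (adjusted p = 2.0e-06; adjusted p = 0.17 with an estimated correlation), a direction that reversed when scaled by total reads. Of 4 NSD2 targets 1 was higher (2 adjusted over the list alone; adjusted p = 0.0013; adjusted p = 0.014 with an estimated correlation). Of 19 immediate early genes 0 passed (2 higher adjusted over the list alone). Of 15 MAPK output genes 1 was higher (2 higher and 2 lower adjusted over the list alone). Neither list passed with camera (adjusted p = 0.12 and 0.38), so their rises with NSD2WT were not shown to exceed the effect of NSD2Y1179A.

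**Figure D3:**
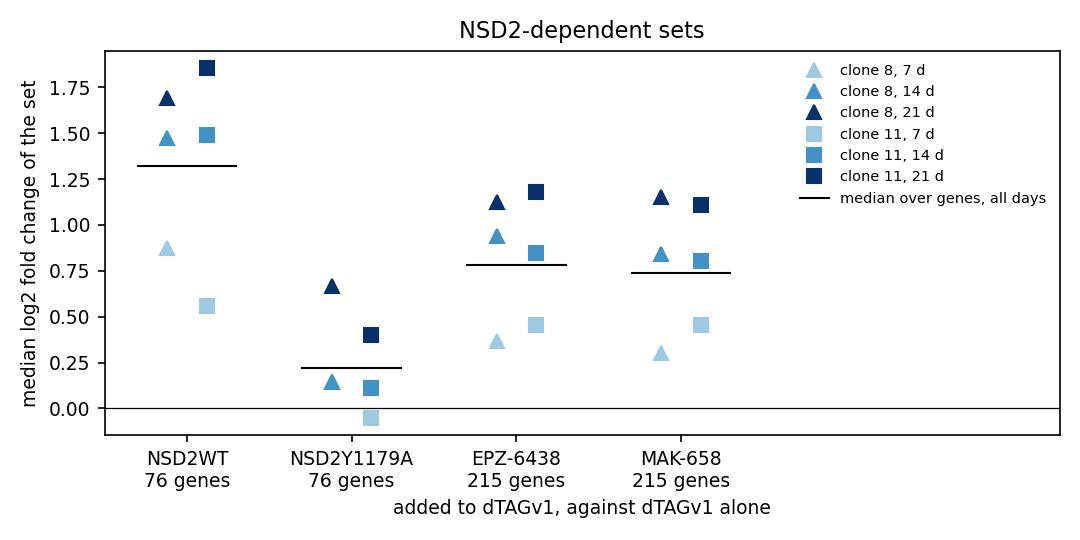
Median log2 fold change of the NSD2-dependent sets on adding NSD2WT, NSD2Y1179A, EPZ-6438 or MAK-658 to dTAGv1, per clone and day (symbols), with the median over genes and days as a line. NSD2WT and both inhibitors lie above 0 in 6 of 6 clone and day values, NSD2Y1179A in 5 of 6.

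NSD2WT raised the 76-gene set, and NSD2Y1179A moved it less. With NSD2WT the median log2 fold change was 1.32, with 64 genes risen, 1 fallen and 11 not passing, and it lay above 0 in 6 of 6 combinations of clone and day (exact sign-flip p = 0.03125, two-sided, the smallest that 6 values allow). With NSD2Y1179A it was 0.22, with 11 genes risen, 1 fallen and 64 not passing, above 0 in 5 of 6 (exact sign-flip p = 0.0625). It lay above all random sets (highest 0.156), and reached 0.67 in clone 8 and 0.40 in clone 11 at 21 d. The value depends on the choices made: it was −0.026 when scaled by total reads, 0.34 in total RNA and 0.14 with all genes that fell whatever their fold (exact sign-flip p = 0.03125 for both of the latter). The difference between both averaged 1.09 over the 6 pairs (lowest 0.61, highest 1.46) and was above 0 in 6 of 6 (exact sign-flip p = 0.03125). The 6 values are days within 2 clones, not independent replicates, so these sign-flip p-values do not measure spread between replicates.

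The inhibitors ask whether PRC2, which methylates H3K27, holds NSD2-dependent genes down once NSD2 is gone. EPZ-6438 at 200 nM was compared with dTAGv1 alone from the days-scale course, 12 libraries each, and the labels do not say whether both sets were run side by side. Genes of TGF-beta and BMP signalling, immediate early genes and NSD2 targets lay higher as groups, and mitosis and unfolded protein response genes lower. Of 9905 genes 594 rose and 207 fell, and 240 and 15 of these changed at least 2-fold. Under scaling by total reads, which shifted all genes by a median of −0.12, 406 rose and 576 fell. The guanylate-binding GBP1 rose by 3.79 (SE 0.38, adjusted p = 7.2e-12), from 1.74 ± 1.52 to 28.1 ± 16.0 T to C reads per M (mean ± SD, n = 12 each). The developmental transcription factor gene NFIB rose by 3.39, CREB5 by 3.12, SAMD11 by 3.08, PRKAA2 by 2.90, FHL2 by 2.71 and S100A10 by 2.68. MX1, an antiviral gene, fell by 1.14, UNC93B1, which carries Toll-like receptors, by 1.12, the class II regulator CIITA by 1.00 and the cytokine gene IL16 by 0.94. Of 20 TGF-beta and BMP genes 8 rose (11 rises and 1 fall adjusted over the list alone; adjusted p = 4.0e-14; adjusted p = 0.00058 with an estimated correlation), ID3 by 2.26, ID1 by 1.96, BMPR2 by 1.68 and TGFB2 by 1.60. Of 20 immediate early genes 8 rose and 1 fell (10 and 2 adjusted over the list alone; adjusted p = 1.6e-09; adjusted p = 4.7e-05 with an estimated correlation), JUN by 1.30 and ATF3 by 1.17. Of 4 NSD2 targets 2 rose, TGFA by 1.76 and PAK1 by 1.19 (4 adjusted over the list alone; adjusted p = 2.9e-06; adjusted p = 0.00027 with an estimated correlation).

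Of 30 mitosis genes 9 fell with EPZ-6438 (19 adjusted over the list alone; adjusted p = 2.9e-09; adjusted p = 0.022 with an estimated correlation), KIF20A by 0.68, the mitotic kinase PLK1 by 0.59 and BUB1 by 0.55. Of 19 unfolded protein response genes 5 fell (6 adjusted over the list alone; adjusted p = 0.00017; adjusted p = 0.015 with an estimated correlation), among them PDIA4 by 0.39 and calreticulin CALR by 0.35. Of 29 PRC2 targets 4 rose and 2 fell (5 and 3 adjusted over the list alone), CDKN2B, a cyclin-dependent kinase inhibitor, rising by 1.44 and HOXB9 by 1.94, and the list did not pass as a group (adjusted p = 0.31). CD74, the invariant chain, fell by 0.84 and TNFRSF13B, which encodes TACI, by 1.09. CDH2 rose by 1.55 and caveolin CAV1 by 1.00, while MZB1 fell by 0.54.

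MAK-658 at 50 nM gave more changes, including HOX genes and a pair of neighbours on chromosome 17. Of 9905 genes 1027 rose and 634 fell, and 309 and 29 of these changed at least 2-fold. Scaled by total reads all genes shifted by a median of −0.22 and the counts were 513 rises and 2727 falls. Canonical PRC2 targets and TGF-beta and BMP genes lay higher as groups, and plasma cell and unfolded protein response genes lower. AATK, a kinase gene of neural cells, rose by 5.75 (SE 0.48, adjusted p = 1.2e-12), from 0.918 ± 1.16 to 36.6 ± 25.5 T to C reads per M (mean ± SD, n = 12 each). Its neighbour BAIAP2 rose by 4.57 (SE 0.34, adjusted p = 4.3e-17). SAMD11 rose by 4.07, CREB5 by 3.50, HDGFL3 by 3.49 and the transcription factor gene NFIA by 3.22. Of 29 canonical PRC2 targets 13 rose and 1 fell (14 and 1 adjusted over the list alone; adjusted p = 4.6e-06; adjusted p = 0.00043 with an estimated correlation). HOXC8 had 61 reads with MAK-658 and 0 without, at least 26.1-fold higher against a floor of 3 reads over the group. HOXC6 had 83 reads against 1, a ratio of 106 with a counting interval of 18.6 to 4251. HOXA11 rose by 3.98 and HOXC9 by 2.97 on the log2 scale.

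Of 20 TGF-beta and BMP genes 10 rose with MAK-658 (11 adjusted over the list alone; adjusted p = 1.0e-15; adjusted p = 0.00034 with an estimated correlation), ID3 by 3.47, ID1 by 2.58, BMPR2 by 1.81 and BMP6 by 1.45. Of 20 immediate early genes 12 rose (13 rises and 3 falls adjusted over the list alone; adjusted p = 2.5e-08; adjusted p = 8.4e-05 with an estimated correlation), including JUN by 1.51 and ATF3 by 1.32. Of 15 plasma cell genes 10 fell and 1 rose (11 and 1 adjusted over the list alone; adjusted p = 1.1e-08; adjusted p = 0.014 with an estimated correlation), SDC1 by 1.33, MZB1 by 1.19 and DERL3 by 0.93. Of 19 unfolded protein response genes 11 fell (12 adjusted over the list alone; adjusted p = 4.2e-08; adjusted p = 0.00034 with an estimated correlation), MANF and PDIA4 both by 0.62 and DNAJB9 by 0.61. Of 30 MYC and ribosome biogenesis genes 13 fell (14 adjusted over the list alone), MRTO4 by 0.51 and POLR1B by 0.45 (adjusted p = 1.2e-05; adjusted p = 0.13 with an estimated correlation). Of 13 myeloma drug and antibody targets 5 fell (5 falls and 1 rise adjusted over the list alone; adjusted p = 0.00997; adjusted p = 0.028 with an estimated correlation): BCMA, encoded by TNFRSF17, by 0.69 and FGFR3, the other gene of the translocation, by 0.47. TGFA rose by 1.14, PAK1 by 0.96 and RRAS2 by 0.84. Of 8 MHC class II genes 4 rose, HLA-DMB by 1.43. MX1 fell by 1.63 and the water channel gene AQP3 by 1.29, while CDKN2B rose by 1.52 and the PRC2 subunit EED by 0.49.

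**Figure D4:**
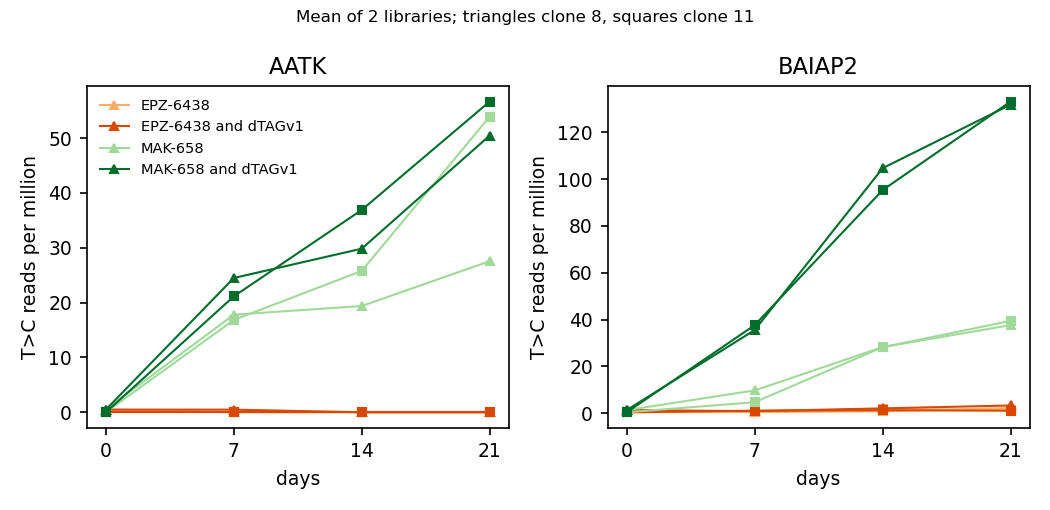
Mean T to C reads per M of AATK and BAIAP2 (2 libraries each) against days with EPZ-6438 or MAK-658, with or without dTAGv1, in clones 8 and 11. Both genes rose with MAK-658 in both clones and stayed near 0 with EPZ-6438.

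Set against each other at these doses, which differ, the inhibitors gave 88 genes higher and 142 lower with EPZ-6438 among 9905. Scaled by total reads these were 314 and 71, and all genes shifted by a median of 0.11. The count of 230 was 148 without the clone 8 library of dTAGv1 with MAK-658 at 14 d, replicate 2. AATK had 1 read with EPZ-6438 against 396 with MAK-658, a ratio of 486 with a counting interval of 86.7 to 19234. BAIAP2 was lower with EPZ-6438 (log2 difference −5.53, SE 0.36, adjusted p = 9.7e-19), as were GJC1 (−2.45), HDGFL3 (−1.84), the Notch target HEY1 (−1.82) and NFIA (−1.19). Of 29 PRC2 targets 7 were lower (9 adjusted over the list alone; adjusted p = 5.8e-08; adjusted p = 8.4e-05 with an estimated correlation). HOXC9 had 2 reads against 119, a ratio of 73.0 with an interval of 19.8 to 610. Of 8 MHC class II genes 5 were lower (6 adjusted over the list alone; adjusted p = 4.3e-10; adjusted p = 0.0016 with an estimated correlation), CIITA by −1.11 and HLA-DRA by −0.84. Of 15 plasma cell genes 9 were higher (10 adjusted over the list alone; adjusted p = 4.9e-14; adjusted p = 0.00064 with an estimated correlation), including SDC1 (0.94), MZB1 (0.65) and CAV1 (0.48). Unfolded protein response genes were also higher (adjusted p = 0.0013; adjusted p = 0.037 with an estimated correlation), with XBP1 at 0.42. TBX2 (1.11), EGR1 (1.25) and ASXL3 (0.79) were higher, and ID2 (−0.97) and ID3 (−1.21) lower.

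Both inhibitors raised the set of genes lowered at least 2-fold in the reconstitution lines, of which 215 of 246 genes were measured. EPZ-6438 gave a median log2 fold change of 0.78, with 94 genes risen and 1 fallen, and MAK-658 gave 0.74, with 87 risen and 5 fallen. Each lay above 0 in 6 of 6 combinations of clone and day (exact sign-flip p = 0.03125). With all genes that fell there, whatever their fold, EPZ-6438 gave 0.10 (exact sign-flip p = 0.03125) and MAK-658 −0.022 (exact sign-flip p = 0.53125). The difference between both inhibitors averaged 0.042 over the 6 pairs (lowest −0.031, highest 0.101), above 0 in 5 of 6 (exact sign-flip p = 0.09375). Here too the 6 values are days within 2 clones, not independent replicates. Whether an inhibitor changed the effect of dTAGv1 itself was tested as an interaction. With inhibitor, dTAGv1 was set against inhibitor alone over the same days, but without inhibitor against 0 d. Time in culture therefore does not cancel in these tests. With EPZ-6438 8 genes passed, all higher, among them INHBE (2.68, SE 0.48, adjusted p = 0.0025) and PRKAA2 (2.01, SE 0.38, adjusted p = 0.0052). Leaving out the 0 d library of clone 8, replicate 1, left 5. With MAK-658 8 genes passed, all higher, including S100A10 (2.22, SE 0.36, adjusted p = 0.00063), KCNS3 (1.87), IGF2BP2 (1.23) and ZNF618 (1.17). Scaled by total reads, all genes shifted by medians of −0.18 and −0.16 in these tests, and the counts were 6 higher with 16 lower for EPZ-6438 and 3 higher with 2 lower for MAK-658.

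The knockout clones ask what lasting loss of NSD2 leaves. Most measured NSD2-dependent genes fell. No gene list had a call that held with an estimated correlation. Each knockout clone gave 1 library, and the control was 2 libraries of 1 parental line. The edgeR common dispersion was 0.0085, against 0.033 to 0.065 in the other comparisons. The tests thus do not cover spread between parental lines. BAIAP2 had 122 T to C reads per M in these parental libraries, against 5.92 in parental cells at 0 h. Differences particular to this parental line are therefore not separated from the knockout. Of 7806 genes 1159 rose and 1131 fell, of which 379 and 507 changed at least 2-fold. These directions are relative to the other labelled reads: scaled by total reads all genes shifted by a median of −0.87, and the counts were 54 rises and 4573 falls. The conversion rate was 0.360% to 0.582% of covered T in the knockout libraries and 1.22% to 1.25% in the parental ones. Leaving out parental replicate 1 or 2 left 1391 or 1308 genes. In total reads 2181 genes rose and 2415 fell, and 1346 of the 2290 genes called in newly synthesised RNA passed there in the same direction, against 73 in the opposite one. Of 1129 falls measured in both, 350 also fell with dTAGv1 in the reconstitution lines, where independent lists would share 78.0. For rises it was 295 of 1158, against 76.4. Of the 76-gene set 40 were measured, 32 fell, and the median log2 fold change was −2.84.

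In the knockout clones the adaptor gene FHL2 had 0 reads against 117 in parental libraries, at least 28.6-fold lower against a floor of 3 reads over the group. GRIP1 had 1 read against 85, a ratio of 62.4 with a counting interval of 10.9 to 2495. SSTR2 fell by 4.15 on the log2 scale (SE 0.48, adjusted p = 3.6e-12) and the RNA-binding protein gene IGF2BP2 by 4.02. CIITA rose by 3.93 (SE 0.45, adjusted p = 4.3e-12), from 4.98 ± 5.59 (n = 2) to 74.3 ± 19.6 (n = 3) T to C reads per M (mean ± SD). DOK4 rose by 3.38 and INSM1 by 2.66. All 5 tested MHC class II genes rose (5 adjusted over the list alone), HLA-DRA by 2.64 and CD74 by 1.60 (camera adjusted p = 1.7e-08; adjusted p = 0.19 with an estimated correlation). Of 19 integrated stress response genes 16 fell (16 adjusted over the list alone; adjusted p = 1.5e-10; adjusted p = 0.32 with an estimated correlation): PHGDH, the first enzyme of serine synthesis, by 2.60, the glycoprotein gene STC2 by 2.58 and CHAC1 by 2.15. Of 18 immediate early genes 11 fell and 5 rose (12 and 5 adjusted over the list alone; adjusted p = 0.0013; adjusted p = 0.30 with an estimated correlation), JUND falling by 1.82 and IER5 rising by 1.63. The p53 targets GADD45A and SESN2 fell by 2.23 and 1.47, the glycolytic enzymes PKM and LDHA by 1.04 and 0.80, CEBPA by 1.92 and DNMT3B by 1.24. SDC1 rose by 2.27 and BIRC3, an inhibitor of apoptosis, by 1.96. POU2AF1, DNMT1 and EED rose by 1.49, 1.24 and 1.14, calls that were not kept when scaled by total reads. AATK had 58 reads in the knockout clones and 0 in parental libraries, at least 26.3-fold higher.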

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

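Tests of other splits of the libraries and of reads shared between AATK and BAIAP2 were chosen after the results were seen; the other tests in this part were written down before their values were seen, though after the patterns they concern. Groups hold 2 or 3 libraries, so no single library was tested against its group.

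The direct tests between groups that passed are those of the clones against parental cells at 21 d (25 genes), NSD2WT against NSD2Y1179A (204 genes, and a mean difference of 1.09 for the 76-gene set), EPZ-6438 against MAK-658 (230 genes), and the interactions of dTAGv1 with EPZ-6438 (8 genes) and with MAK-658 (8 genes). Outside the comparisons of the report, libraries with doxycycline alone or MAK-658 alone also carried signals against 0 d. With doxycycline alone the mitosis genes had a median log2 fold change of −0.60 in the NSD2WT lines and −0.31 in the NSD2Y1179A lines. With MAK-658 alone, canonical PRC2 targets had 0.51, plasma cell genes −0.76 and TGF-beta and BMP genes 0.75. Each lay outside the range of 1000 random lists matched on expression. Such lists do not carry the correlation between genes of a real list. For MAK-658 the 0 d libraries are those of the days-scale course, not of the inhibitor part.

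Mitosis genes fell when either form of NSD2 was re-expressed in depleted cells, 28 of 30 with NSD2WT and 12 of 30 with NSD2Y1179A. Without dTAGv1 the induction alone gave medians of −0.60 and −0.31, with 30 and 25 of the 30 genes below 0, where random lists reached no lower than −0.22 and −0.14. Time in culture is argued against in depleted cells, since dTAGv1 alone over the same days gave −0.0099 in the NSD2WT lines. Untreated cells over these days were not measured, so a fall with time that depletion offsets is not excluded. A candidate explanation for the part common to both is an effect of the induction that needs neither depletion nor catalytic activity, from doxycycline or the construct, which no cells given doxycycline without a construct separate here. Whether the fall is larger with NSD2WT is left open: the median difference in depleted cells was −0.27 (camera adjusted p = 2.0e-06), lost with an estimated correlation (adjusted p = 0.17) and 0.0058 when scaled by total reads.

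AATK and BAIAP2, neighbours on chromosome 17 whose annotated ends overlap, rose together with MAK-658 in depleted cells. Reads of AATK counted as BAIAP2 do not account for this: with all 396 AATK reads taken off the 921 of BAIAP2, 525 remain, against 89 with dTAGv1 alone, and over 2 times as many per M in 6 of 6 combinations of clone and day. Reads of BAIAP2 counted as AATK do not either, since at the share seen with doxycycline alone at 21 d in the NSD2WT lines (42 AATK against 614 BAIAP2 reads) they would bring at most 85.2 of the 396 at the upper counting bound. The knockout clones could not decide it, because BAIAP2 (log2 fold change 0.41) already stood at 122 T to C reads per M in their parental libraries. Parental cells at 0 h of the hours-scale course had a mean of 5.92. A rise in 1 clone alone is argued against by 4.23 in the clone with the lower log2 fold change of AATK. With EPZ-6438, at another dose, neither gene passed, and the dose may be one reason, which was not tested.

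No gene passed in the hours-scale course, while 139 fell at 21 d. A response as large as in the reconstitution lines, hidden by the spread between libraries, was tested with the 76-gene set: its median of −0.45 at 72 h is less than 0.5 times the −1.47 in those lines, in both clones (−0.53 and −0.44). The set lay below the lowest of the random sets (−0.14) and below its own medians at 2, 8 and 24 h, which is consistent with a gradual change. The hours-scale and days-scale libraries are separate sets, and the labels do not say whether they were prepared alike.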

How the results depend on the processing

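Covered T per read as a covariate, alone or with the replicate block, and the omission of libraries low in it were chosen after the data were seen. So were, for the sets, the replicate block, total-read sizes, DESeq2 and the subtraction of random sets; the other alternatives were fixed before. The choice of the most-read transcript was also made after the files were opened: the plan had been the sum over all transcripts of a gene, which is now an alternative. Counts below are of genes past the test. Of 299 counts under an alternative, 176 stayed within 1.5 times the value in the report. For single genes 352 results were followed, most of them for genes named in the report, and 324 of these passed. Over 4895 alternatives of these, 4127 kept their direction and side of the threshold, 747 were no longer past it, 19 came to pass and 2 reversed. Where no reason is given, the cause was not tested.

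Leaving out in turn 1 library of the groups compared gave these ranges, beside the value from all libraries. Counts at 2, 8 and 24 h stayed at 0. The 72 h count went from 0 to 1, that in total RNA from 2 to 3, that of parental cells from 0 to 372, and the interaction at 72 h stayed at 0. For the days-scale course the ranges were 0 to 1 at 7 d (1), 60 to 210 at 14 d (122), 121 to 152 at 21 d (190) and 739 to 824 for total RNA (950). Parental cells at 21 d stayed at 0, and the interaction at 21 d ranged from 6 to 27 (25), but a library of another group in the same fits moved both further, as given below. In the reconstitution lines the ranges were 1375 to 1659 for NSD2WT (1523), 843 to 1200 for NSD2Y1179A (985), 169 to 220 for their difference (204) and 1026 to 1572 for dTAGv1 alone (1375). With inhibitors they were 702 to 818 for EPZ-6438 (801), 1485 to 1775 for MAK-658 (1661), 148 to 281 for the direct comparison (230), 5 to 10 for the interaction with EPZ-6438 (8) and 6 to 10 for that with MAK-658 (8). The knockout count ranged from 1308 to 2261 (2290). Where a group was left with 1 library, that library was taken to vary like the others. Of 7839 such values for single genes, 7619 kept their side of the threshold, 216 lost it, 4 gained it and 0 reversed. For the sets 1 clone at 1 day was omitted in turn, from the median over genes of the mean fold over clones and days, which is not the fitted value of the report. With all 6 it was 1.29 for NSD2WT (1.22 to 1.52), 0.19 for NSD2Y1179A (0.13 to 0.28), 0.85 for EPZ-6438 (0.80 to 0.95) and 0.81 for MAK-658 (0.69 to 0.89).

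The tool and the filter changed mainly small counts. DESeq2 gave 1 gene at 72 h, 10 at 7 d, 191 at 14 d, 12 in total RNA at 72 h and 56 for the interaction at 21 d. It gave 22 for the interaction with EPZ-6438 and 1182 for the knockout, where it also recovered fewer simulated changes than edgeR (42.7% against 66.3%). With no filter the counts were 6 at 72 h, 8 at 7 d, 292 at 14 d, 355 at 21 d, 3 in parental cells at 72 h and 107 for the interaction at 21 d. They were 26 and 19 for the interactions with EPZ-6438 and MAK-658. Summing all transcripts of a gene gave 0 at 7 d and 1384 for the knockout.

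Library sizes from total reads gave 0 at 7 d, 804 for NSD2WT, 762 for dTAGv1 in the reconstitution lines, 3240 for MAK-658 and 385 for the direct comparison of inhibitors. The interactions gave 22 with EPZ-6438 and 5 with MAK-658, and the knockout 4627. Under this scaling the set median with NSD2Y1179A reversed to −0.026, and CCND2 in the knockout reversed to −0.41. The knockout libraries had lower conversion rates (0.360 to 0.582%) than their parental ones (1.22 and 1.25%), and total-read sizes carry such a difference into every fold.

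Replicate numbers were not used as a block, because they do not pair the libraries throughout. Same-numbered libraries of different groups deviated together (correlation over 0.1) in 104 of 105 pairs of groups in the hours-scale course, 31 of 66 in the days-scale course, 707 of 780 in the reconstitution lines and 150 of 276 with inhibitors. The block gave 4 genes at 7 d, 210 at 14 d and 7 in total RNA at 72 h; no other count moved by over 1.5 times. Among these single-gene results 5 lost and 1 gained the call. Covered T per read as a covariate gave 1628 for NSD2Y1179A, 362 for its difference from NSD2WT, 360 for the direct comparison of inhibitors and 6 for the knockout. In the knockout it left few residual degrees of freedom, and there the fitted fold of AATK, with 0 reads in parental cells, reversed to −2.07. The block and covered T together gave 2 genes at 72 h, 10 at 7 d, 383 at 14 d, 334 at 21 d, 10 in total RNA at 72 h and 2272 at 21 d. They gave 35 in parental cells at 21 d, 1584 for NSD2Y1179A, 429 for its difference from NSD2WT and 2168 for dTAGv1 in the reconstitution lines. With inhibitors they gave 500 for the direct comparison and 40 and 21 for the interactions. This fit was not run for the knockout, which leaves it no residual degrees of freedom. Without the libraries low in covered T, in these fits only the parental one at 7 d of replicate 2, the counts were 68 in parental cells at 21 d and 51 for the interaction at 21 d.

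Fits that treat the libraries of a clone otherwise, or use fewer of them, also moved counts. Summing the 2 libraries of a clone and condition gave 16 at 7 d, 508 at 14 d, 423 at 21 d, 0 in total RNA at 72 h and 203 for the interaction at 21 d. It gave 1652 for NSD2Y1179A, 330 for its difference from NSD2WT, 2199 for dTAGv1 in those lines, 466 for the direct comparison and 47 and 19 for the interactions with inhibitors. Means per clone and condition gave 0 at 7 d, 74 at 14 d, 1 in total RNA at 72 h and 140 for the direct comparison. Fits with only the libraries compared gave 2 at 7 d, 77 at 14 d, 0 in total RNA at 72 h, 2 in parental cells at 21 d and 134 for the interaction at 21 d. They gave 653 for NSD2Y1179A, 120 for its difference from NSD2WT and 14 for the interaction with EPZ-6438.

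Each clone alone has fewer libraries and gave fewer calls. Without clone 8 the counts were 0 at 7 and 14 d, 5 at 21 d, and 0 and 42 in total RNA at 72 h and 21 d. The interaction at 21 d gave 0, NSD2WT 420, NSD2Y1179A 26, their difference 5 and dTAGv1 in those lines 227. EPZ-6438 gave 247, MAK-658 413, their comparison 19 and both interactions 0. Without clone 11 the counts were 0 at 7 d, 18 at 14 d, 62 at 21 d, 0 and 452 in total RNA, and 0 for the interaction at 21 d. NSD2WT gave 615, NSD2Y1179A 522, their difference 27 and dTAGv1 459, while EPZ-6438 gave 234, MAK-658 564, their comparison 18 and both interactions 0. Among these single-gene results 177 calls were lost without clone 8 and 120 without clone 11, and 0 reversed.

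Single days have fewer libraries than the mean over days, and gave fewer calls. At 7 d alone NSD2WT gave 263, NSD2Y1179A 20, their difference 1 and dTAGv1 192; EPZ-6438 gave 35, MAK-658 156, their comparison 5 and both interactions 0. At 14 d alone NSD2WT gave 469, the difference 28, EPZ-6438 186, MAK-658 376, their comparison 15 and both interactions 0. At 21 d alone NSD2WT gave 466, NSD2Y1179A 217, their difference 49, EPZ-6438 408, MAK-658 934, their comparison 100 and the interaction with MAK-658 5. The set medians at 7 d alone were 0.69 for NSD2WT and 0.37 for MAK-658. At 21 d alone they were 0.52 for NSD2Y1179A, 1.29 for EPZ-6438 and 1.10 for MAK-658.

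With sets of all genes that fell past the test, whatever their fold, the median was 0.14 for NSD2Y1179A, then past the threshold (exact sign-flip p = 0.03125), and it reversed to −0.022 for MAK-658 (exact sign-flip p = 0.53125). In total RNA NSD2Y1179A gave 0.34, also past it (exact sign-flip p = 0.03125). A set from the 72 h comparison could not be made, since 0 genes passed there. With the correlation estimated by camera 28 of 593 list tests passed, against 91 at the preset one. Power is low in the smaller comparisons, and how far depth sets it was not tested: in simulated libraries 2-fold changes were recovered for 39.9% of genes at 72 h and 0.508% in the interaction at 21 d.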

Other observations

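Tests of other splits of the libraries were chosen after the results were seen, and the test of neighbouring genes was written down before its value was seen.

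With EPZ-6438 alone, in cells with intact NSD2, the NSD2-dependent set of the reconstitution lines lay slightly higher. The median log2 fold change of 215 genes was 0.23 against 0 d, where random lists reached 0.14 at most. Plasma cell genes had a median of −0.38 and mitosis genes −0.27, both below all random lists. The 0 d libraries are those of the days-scale course, so neither part nor time in culture is separated from the inhibitor. Random lists do not carry the correlation between genes of a real list. MAK-658 alone gave 0.16 for the set, inside the random range. AATK had 42 reads in clone 8 and 41 in clone 11 after 7 d of MAK-658 alone, and 1 and 0 at 0 d. In clone 11 at 7 d BAIAP2 had 13 reads, fewer than AATK.

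With dTAGv1 and doxycycline together against 0 d, the 76-gene set was back near its start in the NSD2WT lines, with a median of −0.03, inside the range of random sets. In the NSD2Y1179A lines it stayed at −1.16, with 71 of 76 genes below 0, while TGF-beta and BMP genes stood at 0.54, above all random lists. With dTAGv1 alone the set had −1.41 and −1.37 in these lines. Integrated stress response genes had medians of −0.36 and −0.25 with dTAGv1 alone, and −0.26 and −0.29 with doxycycline added.

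Genes that fell at least 2-fold in the reconstitution lines, 244 with coordinates and reads of their own, were examined for neighbours, since chromatin changes could spread along a chromosome. Of 9164 neighbouring pairs of tested genes 12 had both members among these, including PLPP3 with PRKAA2 and FOXQ1 with FOXF2. Random genes matched on expression gave 0 to 15 such pairs with a median of 6, and 24 of 1000 draws gave as many, so chance placement could not be excluded by that range.

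Other splits of the same libraries were counted for comparisons of groups of 3 or more. At 2, 8, 24 and 72 h all 34 splits gave at least the 0 genes of the real one, so nothing can be read from them; the highest other split gave 0, 111, 0 and 0 genes. The 111 genes at 8 h come from the split of replicate 1 against replicate 2, so structure that follows replicate number, not time, divides those libraries. At 7 d 3 of 34 splits gave 1 gene as the real one did, the split by replicate number among them, and chance cannot be excluded. The real split gave the most genes at 14 d (122, highest other 0) and 21 d (190, highest other 23). It did so too for total RNA at 21 d (950, highest other 374) and at 72 h (2 genes, highest other 0). In each of these 1 of 34 splits, the real one, gave as many. All these splits ignore replicate number, and only 8 keep clone and replicate number together. Whether chance gave these counts can therefore not be told from them. The 23 and the 374 genes at 21 d also come from the split by replicate number. The split of clone 8 against clone 11 could not be fitted beside the clone term.

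For the larger comparisons 60 splits within each day were drawn, the real one included. The real and highest other counts were 1523 and 107 for NSD2WT, 985 and 293 for NSD2Y1179A, 204 and 1 for their difference, and 1375 and 33 for dTAGv1 in those lines. They were 801 and 274 for EPZ-6438, 1661 and 24 for MAK-658, and 230 and 109 for the direct comparison. Here 1 split of 60, the real one, gave as many, so the real grouping stood out from those drawn. These splits ignore replicate number, so they do not exclude chance on their own. For each inhibitor against dTAGv1 alone, the real split also parts inhibitor libraries from days-scale libraries. It cannot tell an inhibitor effect from a difference between these parts. For the interactions 2 of 60 splits gave as many, with 8 genes against a highest other of 21 for EPZ-6438 and 9 for MAK-658. In both, a split without meaning gave more genes than the real one, and the 21 genes point to structure among those libraries, so the 8 genes of either interaction carry less weight than that share alone would give them.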
